A study of Mus musculus with 6 samples.

How the data were processed

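Open chromatin was measured by ATAC-seq, in which the transposase Tn5 cuts accessible DNA and adds sequencing adapters, in insulin-producing β-cells of the mouse pancreas. Per the labels, the cells came from dispersed islets of tamoxifen-treated mice and were sorted by flow cytometry for the red fluorescent protein Tomato. Between 27000 and 80000 sorted cells gave between 14000 and 45000 nuclei for each tagmentation, and fragments above 600 bp were removed from the libraries. The genotype label put 3 libraries in a control group and 3 in a Chd4 knockout group. The labels do not say whether the libraries of a group came from separate animals. P-values of tests between libraries therefore measure the spread between these samples, which may be technical. Tests with regions or genes as units do not measure it. The control and knockout libraries carry the replicate numbers 1 to 3 in their titles.

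Each library has its own deposited list of narrow peaks, so replicates were not pooled. The peak names inside the deposited files point to MACS2 run on shifted cutting sites. Its version and settings, the aligner and the read filters are not given in the sources used here. The genome build was mm10 per the submitters' processing notes. Per the values in the deposited files, every peak has a −log10 q above that of q = 0.05 and is at least 200 bp wide. The score in the deposited lists is 10 times the −log10 q as a whole number, and the authors' files also give a fold enrichment at the summit as a ratio, a −log10 p and a −log10 q for each peak. These values per peak are the authors' own and were used only to describe, rank or filter peaks within a list. The lists hold no read counts, so the depth of each library is unknown, and no confidence interval based on counted reads could be given. The number of peaks called depends on depth and signal over background as well as on open chromatin.

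Peaks of all 6 libraries were merged into regions wherever they overlapped by at least 1 bp, and a region was called in a library if a peak of that library overlapped it. Regions called in all 3 knockout libraries and in no control library are termed gained, and the reverse are termed lost. Regions called in exactly 3 libraries of mixed genotype served as the comparison set. The number of gained and lost regions expected from differences between libraries in how much was called came from a log-linear Poisson model with a term per library, fitted to the 18 mixed patterns of 3 libraries.

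Genes were 21887 protein-coding genes of the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. The table used gives gene spans without strand or exons, so promoters, exons, introns and untranslated regions were not told apart. Instead, a peak within 1 kb of either end of a gene span was placed at a gene end, otherwise within a gene if it overlapped a span, and otherwise between genes. For each gene, the covered length was the number of bases under peaks in the gene span plus 10 kb on either side. Covered length was scaled so that every library had the mean total, 300 bp were added and the log2 was taken. Genes with a mean unscaled covered length of at least 300 bp were tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on the scale of log2(covered length + 300 bp), which understates changes of genes with few peaks. Covered length responds to how many peaks are called and how wide they are and is not a read count.

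Per-library values were compared with two-sided exact permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. Locations of gained and lost regions were compared with mixed regions by two-sided Fisher exact tests, whose p-values are too small because neighboring regions are not independent. Regions are the units of these tests, so the p-values do not measure the spread between libraries. A set of 24 gene lists was fixed before the data were examined. It covered β-cell transcription factors, insulin secretion, β-cell maturation, dedifferentiation and disallowed genes, other islet cells, acinar, ductal, endothelial, blood and mesenchymal cells, neurons, muscle, liver, chromatin complexes, stress, metabolism, the cell cycle and housekeeping genes. All listed genes were found in the annotation, 2 of them through synonyms. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Camera compares a list with the other genes, while fry tests whether the list itself differs between the groups. Gained and lost regions in the territories of each list were set against 10000 random lists matched in 40 bins on the number of regions per gene. The permutation p of a list is its two-sided position among these lists. Genes were drawn for it and libraries were not exchanged, so it does not measure the spread between libraries. A region in the territories of more than 1 member counted once for each. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.

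Genes were named by a rule fixed before the data were examined. It took Chd4, then preset genes (Ins1, Ins2, Pdx1, Mafa, Nkx6-1, Neurod1, Slc2a2, Ucn3, G6pc2, Slc30a8, Glp1r, Gcg and Sst). It then took the 10 largest positive and 10 largest negative fold changes among genes past the threshold whose knockout values all lay on the same side of the control values, leaving out predicted Gm and Rik models. Last came up to 4 members of each list past the threshold by absolute fold change. Regions named for a gene are at most 3 gained or lost regions in its territory, the widest first. Some genes that the rule selects are not reported here, but they stay in the tests and counts.

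Simulated data tested the procedures. With 200 of 17711 genes changed by 0.5 on the log2 scale in the comparison of knockout and control, 20.5% were called, and with a change of 1, 91% were called. All calls of changed genes had the right direction, and false calls numbered 0 and 1. Residuals were shuffled separately for each gene, and as many genes were raised as lowered. Shared territories and the effect of scaling were therefore not simulated. In simulated regions without planted changes, the ratios of gained and lost regions to the expected counts were 1.01 and 0.900. Calls there were drawn independently at 1 rate per library, so weak sites were not simulated.

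Alternatives were a −log10 q of at least 5, the 50000 strongest peaks of each library, regions joined from summits within 150 bp, a peak over at least 50% of a region, no scaling, quantile normalization, pseudocounts of 100 and 1000 bp, no filter on low values, the replicate number as a block, and each library left out in turn. The gene-end definition with its 5 kb alternative, the gene span plus 50 kb, the gene span alone and the nearest gene span replaced intended definitions that need a transcription start, and were chosen after the annotation had been seen. The planned motif analysis was not run, because no genome sequence was used here.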

Results

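The series compared open chromatin in β-cells, the insulin-producing cells of the pancreatic islets, between control mice and mice in which Chd4 was knocked out. Chd4 is the ATP-dependent helicase of the NuRD chromatin remodeling complex, and the comparison asks how its loss alters chromatin accessibility in mature β-cells. ATAC-seq peak lists of 3 control and 3 knockout libraries were available. Control libraries 1 to 3 held 100109, 110693 and 101289 peaks, and knockout libraries 1 to 3 held 122730, 124125 and 119088. The depth in reads is unknown for every library. Any pair of libraries of the same genotype shared regions with a Jaccard index of 0.785 to 0.825, while pairs of different genotype shared 0.626 to 0.647, and no library repeated another.

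More peaks were called in the Chd4 knockout libraries than in the control libraries, mainly away from gene ends. The knockout libraries held 121981 ± 2601 peaks (SD, n = 3) and the control libraries 104030 ± 5800, a ratio of 1.17 (two-sided exact permutation test, p = 0.1, the smallest p possible with 3 against 3). Peaks between genes numbered 48007 ± 279 in the knockout and 37433 ± 2449 in the control, a ratio of 1.28. Peaks at gene ends numbered 16512 ± 124 and 16001 ± 163, a ratio of 1.03. All knockout values lay above all control values in each of these comparisons. The share of peaks at gene ends was accordingly 13.5% ± 0.19 in the knockout and 15.4% ± 0.68 in the control (exact permutation p = 0.1). With the 50000 strongest peaks of each library the difference in this share was -0.37 percentage points in place of -1.87, and the groups overlapped (exact permutation p = 0.2). Peaks covered 67.5 ± 1.7 Mb in the knockout and 60.0 ± 3.3 Mb in the control, with median widths of 481 ± 4.6 and 494 ± 5.3 bp.

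**Figure D1:**
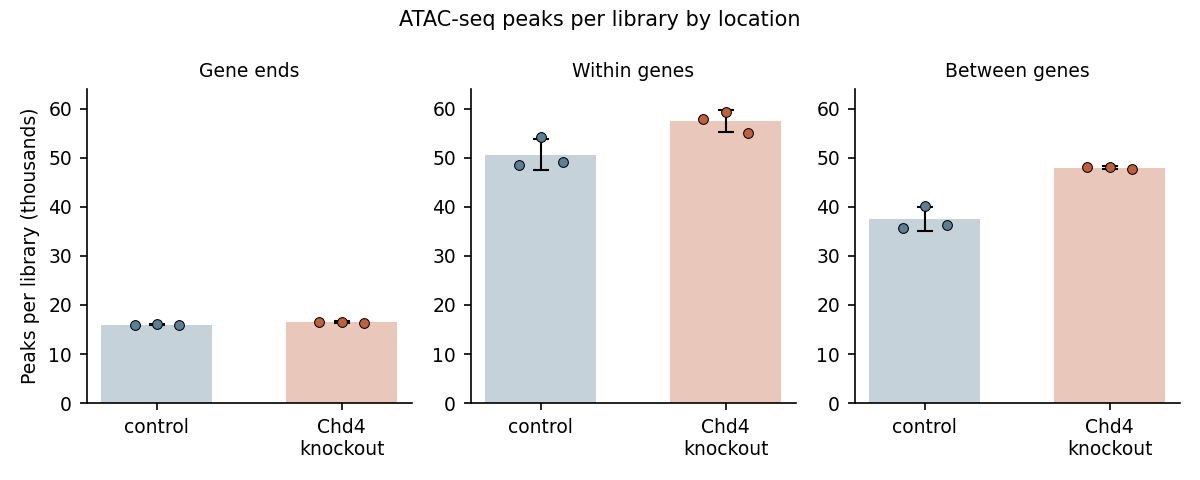
Peaks per library (vertical axis, in units of 1000) at gene ends, within genes and between genes in 3 control and 3 Chd4 knockout libraries; bars are means, error bars SD and points single libraries. Between genes the knockout mean was 48007 peaks against 37433 in the control, and at gene ends 16512 against 16001.

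Many regions were called in every knockout library and in no control library, and a smaller set showed the reverse. Of 156745 regions, 75312 were called in all 6 libraries. Gained regions numbered 16193, which was 97.2 times the 167 expected from the model with a term per library. Lost regions numbered 4113, which was 21.4 times the expected 193. The model treats calls as independent between libraries and was fitted to mixed patterns alone. The ratios therefore do not exclude a calling difference that the libraries of a group share at the same sites. The next most frequent set of 3 libraries shared 478 regions. Peaks of gained regions were narrow, with median widths of 323 to 332 bp in the knockout lists, and their authors' −log10 q had median percentiles of 32.9 to 35.7 within those lists. Peaks of lost regions had median percentiles of 21.7 to 27.99 in the control lists. With the 50000 strongest peaks of each library, 5782 regions were gained and 4562 lost, so the ratio of gained to lost regions was 1.27 in place of 3.94. Without control library 1, 6188 regions were lost. Leaving out each library in turn gave ratios to the expected number of 92.1 to 187 for gained and 36.8 to 88.7 for lost regions, the highest of both without control library 1.

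**Figure D2:**
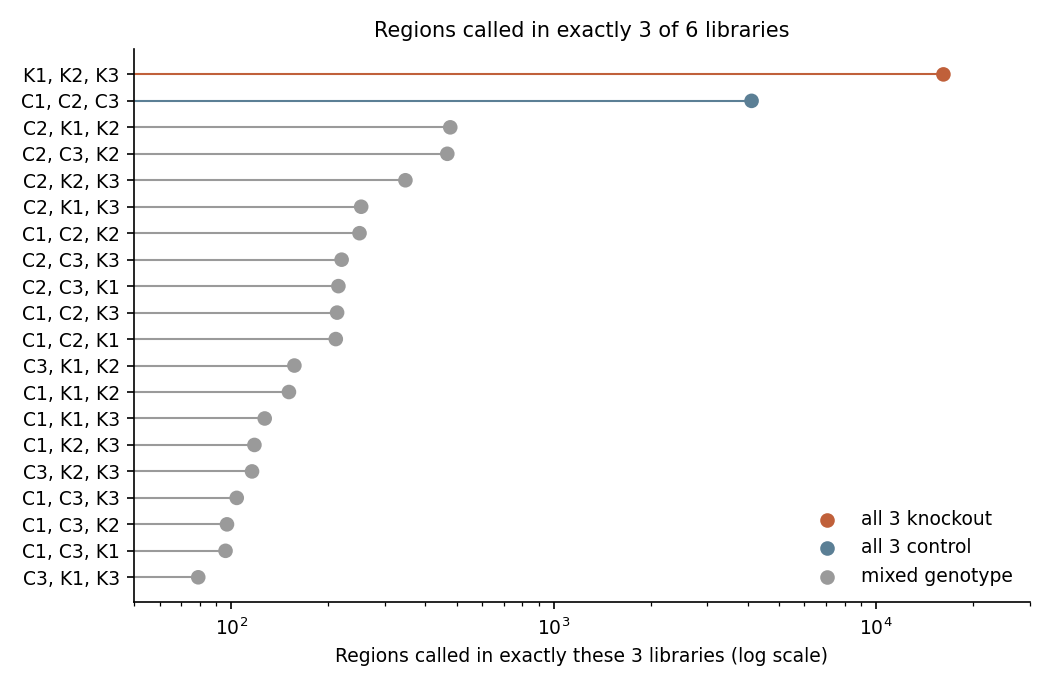
Number of regions (log axis) called in exactly the 3 libraries named on the vertical axis, where C is control and K knockout, for all 20 combinations. The 3 knockout libraries alone shared 16193 regions and the 3 control libraries alone 4113, while no mixed set exceeded 478.

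Gained regions lay between genes more often than regions called equally often without regard to genotype. Between genes lay 50.9% of gained, 34.6% of lost and 37.3% of the 3700 mixed regions (gained against mixed, odds ratio 1.74, Fisher exact p = 4.2e-51; lost against mixed, odds ratio 0.888, p = 0.012). The most frequent mixed sets of 3 libraries, with 478, 468 and 347 regions, all held control library 2. Without that library the odds ratios between genes were 1.80 for gained and 0.661 for lost regions (Fisher exact p = 2.7e-77 and 2.5e-32). Gene ends held 3.85% of gained, 5.86% of lost and 4.38% of mixed regions, but 19.0% of regions called in all 6 libraries. The odds ratio at gene ends was 1.36 for lost (Fisher exact p = 0.0035) and 0.875 for gained regions (p = 0.15). With regions joined from summits the odds ratio of lost regions was 0.824 at gene ends and 1.02 between genes (Fisher exact p = 0.0099 and 0.65), both in the opposite direction, and with the 50000 strongest peaks it was 1.02 at gene ends (Fisher exact p = 0.95). Gained regions at gene ends passed with regions joined from summits (odds ratio 0.458, Fisher exact p = 1.0e-33), a peak over at least 50% of the region (0.778, p = 0.0010), the 50000 strongest peaks (0.730, p = 0.011) and any library left out (0.588 to 0.728), but had 1.04 with gene ends of 5 kb (Fisher exact p = 0.49). At regions called in all 6 libraries, the mean covered length between genes was 611 ± 3.8 bp per region in the knockout and 588 ± 16 bp in the control (exact permutation p = 0.1), and at gene ends 978 ± 15 and 988 ± 12 bp (exact permutation p = 0.5).

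At Chd4 itself (chromosome 6, 125095980 to 125130591), 8 regions lay in the gene territory and none was gained or lost. Covered length, given for genes in bp after scaling to the mean total, was 5079 ± 404 bp in the knockout and 5692 ± 361 bp in the control (log2 fold change -0.16 ± 0.08 SE, limma adjusted p = 0.17; 0.01 without scaling). The peaks do not show a deletion of exons, so they do not check the genotype labels.

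Covered length fell at Ins1, an insulin gene, and at genes of the transcription factors Mafa and Neurod1, which bind insulin promoters. At Ins1 (chromosome 19, 52264297 to 52265015) covered length was 2768 ± 189 bp in the knockout and 4414 ± 251 bp in the control, with no overlap between the groups (log2 fold change -0.62 ± 0.07 SE, limma adjusted p = 0.0025). Of 6 regions near Ins1, 5 were called in all 6 libraries, and in each of these peaks covered fewer bases on average in the knockout, with and without scaling. Peaks over the gene (52263799 to 52264905) covered 854 ± 27 bp in the knockout and 1098 ± 5.3 bp in the control, without scaling. In the neighboring region, 265 bp from the gene (52265280 to 52266622), peaks covered 773 ± 279 and 1139 ± 97 bp, also without scaling. At Mafa (chromosome 15, 75745501 to 75748321) covered length was 3644 ± 344 bp against 5132 ± 312 bp in the control (log2 fold change -0.46 ± 0.08, limma adjusted p = 0.010). At Neurod1 (chromosome 2, 79452637 to 79456636) it was 2961 ± 325 bp against 4242 ± 359 bp (log2 fold change -0.48 ± 0.09, limma adjusted p = 0.013). A region 9101 bp from Neurod1, between genes (chromosome 2, 79442933 to 79443536), was lost. Glp1r, the receptor of the incretin GLP-1, fell by 0.24 ± 0.06 (limma adjusted p = 0.027) and contained a lost region within the gene (chromosome 17, 30905180 to 30905485).

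The fall at Ins1 passed the threshold without scaling as well (log2 fold change -0.46, limma adjusted p = 0.0058). Without scaling, Mafa (-0.30, limma adjusted p = 0.057), Neurod1 (-0.32, limma adjusted p = 0.057) and Glp1r (-0.08, limma adjusted p = 0.36) did not pass, and with the 50000 strongest peaks Neurod1 (0.01) and Glp1r (0.31) had the opposite sign. The other preset genes named here did not pass. Ins2, the other insulin gene, had a log2 fold change of -0.24 ± 0.14 (limma adjusted p = 0.23), Nkx6-1 of -0.25 ± 0.08 (limma adjusted p = 0.059), the urocortin gene Ucn3 of -0.24 ± 0.08 (limma adjusted p = 0.071) and the glucose-6-phosphatase gene G6pc2 of -0.19 ± 0.07 (limma adjusted p = 0.068). The glucose transporter gene Slc2a2 had -0.15 ± 0.09, the zinc transporter gene Slc30a8 -0.10 ± 0.08, the glucagon gene Gcg -0.19 ± 0.11 and the somatostatin gene Sst -0.15 ± 0.12. The territory of Slc2a2 held 2 gained regions and 1 lost region, that of Ucn3 1 of each, and that of G6pc2 1 gained region. Pdx1, a master regulator of β-cells, had 0.10 ± 0.06 (limma adjusted p = 0.29) and a gained region 8568 bp from the gene (chromosome 5, 147284416 to 147284707). Without scaling Pdx1 had 0.26 and passed (limma adjusted p = 0.026).

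**Figure D3:**
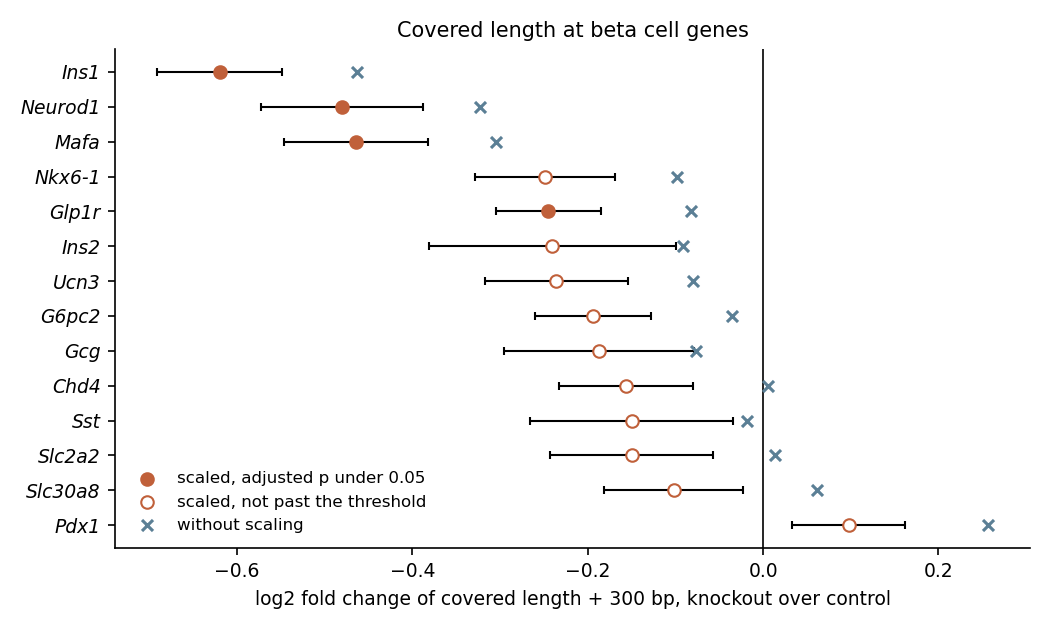
Log2 fold change of covered length plus 300 bp (knockout over control, horizontal axis) at Chd4 and 13 preset genes; circles are scaled values with SE, filled where the limma adjusted p passed 0.05, and crosses are values without scaling. Ins1 lay at -0.62 with scaling and -0.46 without, and Pdx1 was the gene farthest to the right, at 0.10 and 0.26.

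**Figure D4:**
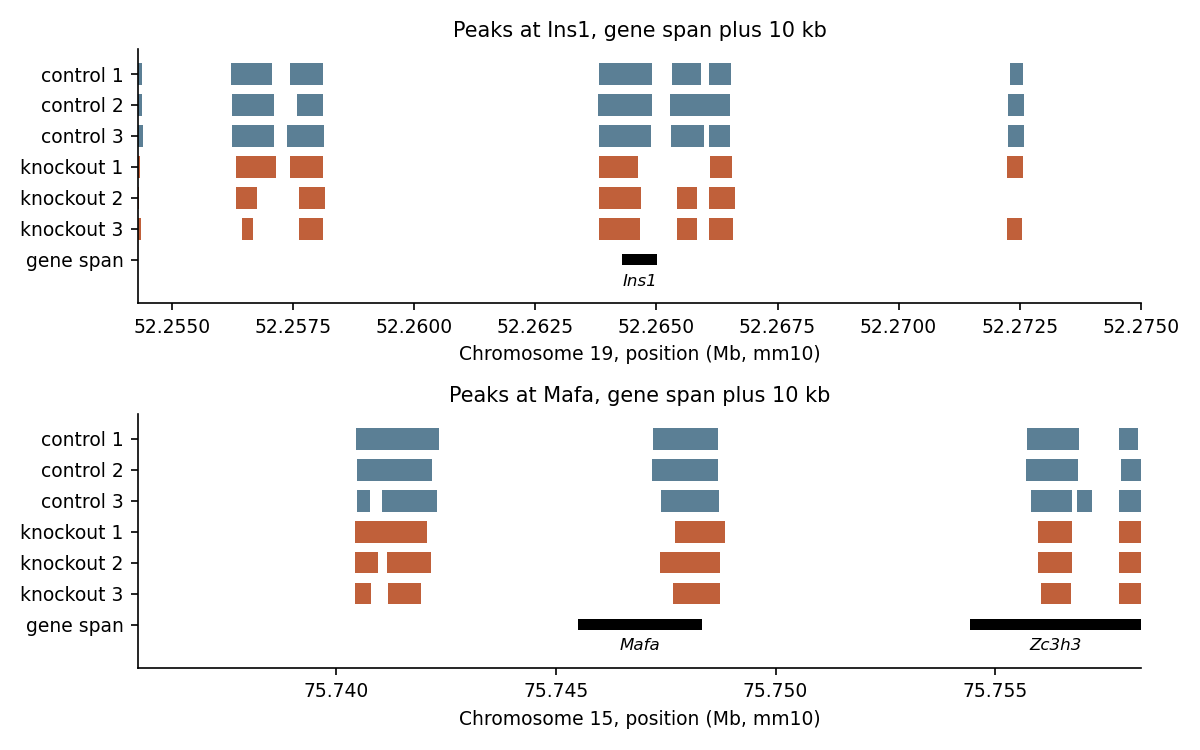
Peaks of each library along chromosome 19 at Ins1 and chromosome 15 at Mafa (position in Mb, mm10; gene span plus 10 kb, where peaks are cut at the edges), with control libraries in blue, knockout libraries in orange and gene spans in black. At Ins1 the peak over the gene was shorter in all 3 knockout libraries, with a mean of 854 bp against 1098 bp.

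Across 17711 genes, covered length was higher in the knockout at 1340 and lower at 2577 (limma adjusted p under 0.05). These fall into 1131 and 1894 separate loci, since 80.4% of called genes share their territory with another gene. The groups did not overlap at 45.8% of genes, where chance gives 10%. The scaling sets the balance of these calls. Without it 2586 genes were higher and 510 lower, the share of higher genes among calls went from 34.2% to 83.5%, and the median of all genes moved by 0.15. Of the calls, 1324 higher and 510 lower genes passed in both. Leaving out control library 3 left 723 higher and 840 lower genes, and leaving out knockout library 1 left 676 and 1156. Without control library 1, 1145 genes were lower, and without knockout library 2, 829 were higher and 1560 lower.

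Of the genes named by the rule, the largest gains on the log2 scale stood at genes where control libraries had few or no peaks. Dpysl4, a dihydropyrimidinase-like gene of the nervous system (chromosome 7, 139085981 to 139101795), was listed at 0 bp in every control library and had 1734 ± 157 bp in the knockout (limma adjusted p = 4.0e-04). Its widest gained region lay at the gene end (139085625 to 139086681, 1057 bp). Zfp993, a zinc finger gene, had 1324 ± 273 bp in the knockout and 0 bp in every control library. The same held for the neighbors Prr23a2 and Prr23a3, which share all their peaks (1169 ± 28 bp), Entpd8, an ectonucleotidase gene (1045 ± 142 bp), Fndc3c1 on the X chromosome (1036 ± 139 bp), Wfdc5 (1068 ± 576 bp) and Serpina1d, an α1-antitrypsin gene of the liver (1031 ± 279 bp). Sod3, the extracellular superoxide dismutase gene, had 1441 ± 201 bp against 79 ± 136 bp in the control. Sh3rf2 had 3025 ± 190 bp against 418 ± 362 bp, with 4 gained regions. All 10 passed without scaling too.

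Among the 10 largest losses on the log2 scale, 4 genes were listed at 0 bp in every knockout library. Zic2, a zinc finger factor of the developing brain (chromosome 14, 122475384 to 122480328), had 124 ± 214 bp in the knockout and 1382 ± 179 bp in the control (log2 fold change -2.09 ± 0.30 SE, limma adjusted p = 0.0057). The forkhead gene Foxd4 had 907 ± 173 bp in the control and was listed at 0 bp in every knockout library. Its lost region lay inside the gene span, within 1 kb of an end (chromosome 19, 24899384 to 24900584). Tal2, a helix-loop-helix factor gene, had 687 ± 145 bp in the control, Emilin3 749 ± 252 bp and Trim12a 1011 ± 384 bp, each listed at 0 bp in every knockout library. The neuropeptide Y receptor gene Npy2r had 143 ± 126 against 1337 ± 38 bp (log2 fold change -1.93 ± 0.22, limma adjusted p = 0.0024). Lrrtm1, a synaptic adhesion gene, had 264 ± 308 against 1782 ± 264 bp, the synaptotagmin gene Syt10 63 ± 109 against 812 ± 301 bp, Gpr141 82 ± 142 against 894 ± 123 bp, and the GABA receptor gene Gabra2 551 ± 483 against 1815 ± 159 bp. Without scaling Gabra2 did not pass (limma adjusted p = 0.11), and the other 9 did.

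Genes of β-cell identity and function that passed were mostly lower, though no β-cell list as a whole stood apart from other genes. Lower calls were also the more frequent among all 17711 genes with scaling, at 2577 against 1340 higher. Of 45 insulin secretion genes, 12 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median log2 fold change of -0.15 (camera adjusted p = 0.080; adjusted p = 0.72 with an estimated correlation). Besides Ins1, the neuropeptide Y receptor gene Npy1r (-0.77 ± 0.13), the oxidoreductase gene Ero1b, which acts in insulin folding (-0.54 ± 0.15), and the potassium channel gene Kcnk16 (-0.46 ± 0.06) fell. With the gene span plus 50 kb, Npy1r had the opposite sign (0.10). Without scaling 3 genes of the list were lower and 2 higher, and the median was 0.01. With 1 library left out in turn, 4 to 9 were lower and 1 to 2 higher. Of 30 β-cell transcription factor genes, 5 were lower, among them Six3 (-0.45 ± 0.09), and 1 was higher (camera adjusted p = 0.49). That gene was Hnf4a, a nuclear receptor of liver and islets, at 5048 ± 472 bp in the knockout and 3318 ± 93 bp in the control (log2 fold change 0.56 ± 0.08 SE, limma adjusted p = 0.0046; 0.72 without scaling). Its territory held 2 gained regions within the gene, the wider at chromosome 2, 163564085 to 163564887, and 1 lost region (163525683 to 163525980). Of 17 maturation genes, 4 were lower, with the cation channel gene Trpm5 at -0.35 ± 0.10 (camera adjusted p = 0.49). Without scaling 0 of the maturation genes passed, and 3 transcription factor genes were higher and 0 lower. Leaving out 1 library left 1 to 4 lower maturation genes and 3 to 5 lower transcription factor genes.

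Genes that β-cells normally shut off, and genes of immature or dedifferentiated β-cells, went both ways. Of 18 dedifferentiation and progenitor genes, 3 were higher, among them Serpina7 (1.20 ± 0.36) and the cholecystokinin gene Cck (0.50 ± 0.15), and Pou5f1 was lower (-0.60 ± 0.09; camera adjusted p = 0.24). Of 20 disallowed genes, Acot7 (0.35 ± 0.10), Lsp1 (0.44 ± 0.11) and Oat (0.37 ± 0.08) were higher and Cxcl12 lower (-0.28 ± 0.08), or 2 and 0 adjusted over the list alone (camera adjusted p = 0.49). Without scaling Serpina7 and Cxcl12 did not pass.

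Of 20 α-cell genes, 5 were lower and 1 higher (5 and 3 adjusted over the list alone). The homeobox genes Irx1 (-0.63 ± 0.10) and Irx2 (-0.51 ± 0.06) fell, each with a lost region over a gene end, as did Fap (-0.77 ± 0.16), while Ldb2 (0.49 ± 0.09) rose. Without scaling 3 α-cell genes were lower and 3 higher. Of 13 δ-, γ- and ε-cell genes, 2 were lower, the homeobox gene Hhex (-0.61 ± 0.07) and Shisal2b (-0.59 ± 0.08). Irx2 (0.27) and Hhex (0.67) had the opposite sign with the 50000 strongest peaks. Of 12 acinar genes, 2 were higher and none lower (3 and 2 adjusted over the list alone), the chymotrypsinogen gene Ctrb1 (1.09 ± 0.15), with 3 gained regions near it, and the elastase gene Cela2a (0.59 ± 0.13). Of 15 ductal genes, Onecut2 (0.35 ± 0.08) was higher, and Spp1 (-0.48 ± 0.07) and Cldn7 (-0.32 ± 0.06) were lower. None of these lists passed (camera adjusted p = 0.97, 0.96, 0.24 and 0.73).

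Among vessel, blood and connective tissue markers, the endothelial genes Eng (from 345 ± 25 to 1308 ± 270 bp) and Erg (0.90 ± 0.13) rose, and Emcn (-1.10 ± 0.31) and Sox17 (-0.91 ± 0.27) fell, 2 higher and 3 lower of 15 in all. Of 15 macrophage and leukocyte genes, Cd74 (0.50 ± 0.10) and Itgb2 (0.48 ± 0.11) were higher and Spi1 (-0.39 ± 0.09) and C1qc (-0.28 ± 0.07) lower, with 2 and 5 adjusted over the list alone. Of 14 mesenchymal genes, Pdgfrb (0.79 ± 0.11) and Prrx1 (0.44 ± 0.12) were higher and none lower, with 1 adjusted over the list alone. Cd74 (-0.77) and Pdgfrb (-1.22) had the opposite sign with the 50000 strongest peaks, and with the gene span plus 50 kb C1qc (0.10) did. The lists did not pass (camera adjusted p = 0.37, 0.96 and 0.24). Without scaling Emcn, Sox17, Spi1 and C1qc did not pass.

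The neuronal list was the only list past the camera threshold. Of 30 neuronal genes, 4 were higher and 1 lower, with a median log2 fold change of 0.05 (camera adjusted p = 0.042; adjusted p = 0.72 with an estimated correlation). The kinase gene Camk2a rose from 2262 ± 282 to 4955 ± 42 bp (log2 fold change 1.04 ± 0.08 SE, limma adjusted p = 0.0011) and held 4 gained regions, the widest within the gene (chromosome 18, 60947642 to 60948306). Csmd1 (0.77 ± 0.14) and the NMDA receptor gene Grin2b (0.68 ± 0.11), with 5 gained regions each, also rose. Without scaling the list did not pass (camera adjusted p = 0.28), and it did not with the 50000 strongest peaks, quantile normalization, the gene span plus 50 kb or no filter on low values (camera adjusted p = 0.34, 0.15, 0.18 and 0.071). Without control library 1, control library 3 or knockout library 3 it did not pass either. Of 24 muscle genes, 6 were higher and none lower (8 and 1 adjusted over the list alone), among them the myosin genes Myh7 (0.98 ± 0.17) and Myh6 (0.59 ± 0.18), the troponin gene Tnni2 (0.64 ± 0.15) and the calcium release channel gene Ryr1 (0.53 ± 0.08; camera adjusted p = 0.075). Myh6 and Myh7 are neighbors with overlapping territories and share their gained region, so they are not independent. With 1 library left out in turn, 3 to 6 muscle genes were higher and 0 lower. Of 19 liver genes, 2 were higher, Otc (0.69 ± 0.16) and Hpd (0.53 ± 0.11; camera adjusted p = 0.23). Myh6 (-0.19) and Hpd (-0.14) had the opposite sign with the 50000 strongest peaks, as they did with the gene span plus 50 kb (-0.10 and -0.0478), and Hpd did with the gene span alone (-0.20).

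Stress, respiration and cell cycle genes that passed were lower, which was the more frequent direction among all called genes with scaling. Of 20 genes of the unfolded protein response, 6 were lower (7 lower and 1 higher adjusted over the list alone), with Atf4 at -0.34 ± 0.06, Pdia4 at -0.33 ± 0.07, Sel1l at -0.31 ± 0.07 and Xbp1 at -0.30 ± 0.06. Of 22 oxidative phosphorylation genes, 7 were lower, with Atp5a1 at -0.54 ± 0.06, Uqcrc2 at -0.33 ± 0.09 and Atp5b at -0.27 ± 0.06. Of 28 cell cycle genes, 8 were lower, with Plk1 at -0.61 ± 0.09, Mcm3 at -0.49 ± 0.10, Mcm6 at -0.45 ± 0.09 and the inhibitor gene Cdkn1b at -0.41 ± 0.06. These lists did not pass (camera adjusted p = 0.24, 0.37 and 0.096). Without scaling the lower members numbered 0, 1 and 3, and the higher 1, 3 and 1. With 1 library left out in turn, the lower members numbered 2 to 5, 2 to 6 and 6 to 9. Of 22 immediate early genes, Jun (-0.35 ± 0.08), Egr1, Fosl1 and Fosl2 were lower (camera adjusted p = 0.23), and of 20 DNA damage and p53 genes, Fas (-0.34 ± 0.08), Trp53 and Bax (camera adjusted p = 0.28; 2 lower adjusted over the list alone). Without scaling 0 genes of both lists passed. With 1 library left out in turn, 0 to 5 immediate early genes and 0 to 4 DNA damage and p53 genes were lower. Of 20 glycolysis genes, Pgam2 was higher and Aldoa lower (camera adjusted p = 0.24), and of 20 housekeeping genes, Psmb2 and Sdha were lower (camera adjusted p = 0.92). Atp5a1 (0.20), Plk1 (0.00748), Egr1 (0.0838), Fosl2 (0.00392) and Psmb2 (0.16) had the opposite sign with the 50000 strongest peaks. With the gene span plus 50 kb Mcm3 (0.0653), Egr1 (0.10), Fosl2 (0.0582), Trp53 (0.00186) and Sdha (0.0902) did.

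Among chromatin remodeling genes, calls went both ways. Of 15 NuRD genes, Hdac2 (-0.35 ± 0.09), Mta1 (-0.28 ± 0.06) and Cdk2ap1 (-0.25 ± 0.07) were lower (camera adjusted p = 0.96). Of 19 SWI/SNF genes, Smarcc1 (0.34 ± 0.10) and Smarcc2 (0.28 ± 0.07) were higher and Dpf1 (-0.40 ± 0.10) and Arid1b (-0.19 ± 0.06) lower, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.92). With 1 library left out in turn, 0 to 2 NuRD genes were lower and 0 to 1 higher. Likewise 0 to 2 SWI/SNF genes were higher and 0 to 1 lower. Without scaling none of the lower genes of both lists passed, and with the 50000 strongest peaks Hdac2 (0.0408), Mta1 (0.0624), Smarcc1 (-0.35) and Arid1b (0.16) had the opposite sign. In lists for which no other number is given, adjustment over the list alone gave the same counts.

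**Figure D5:**
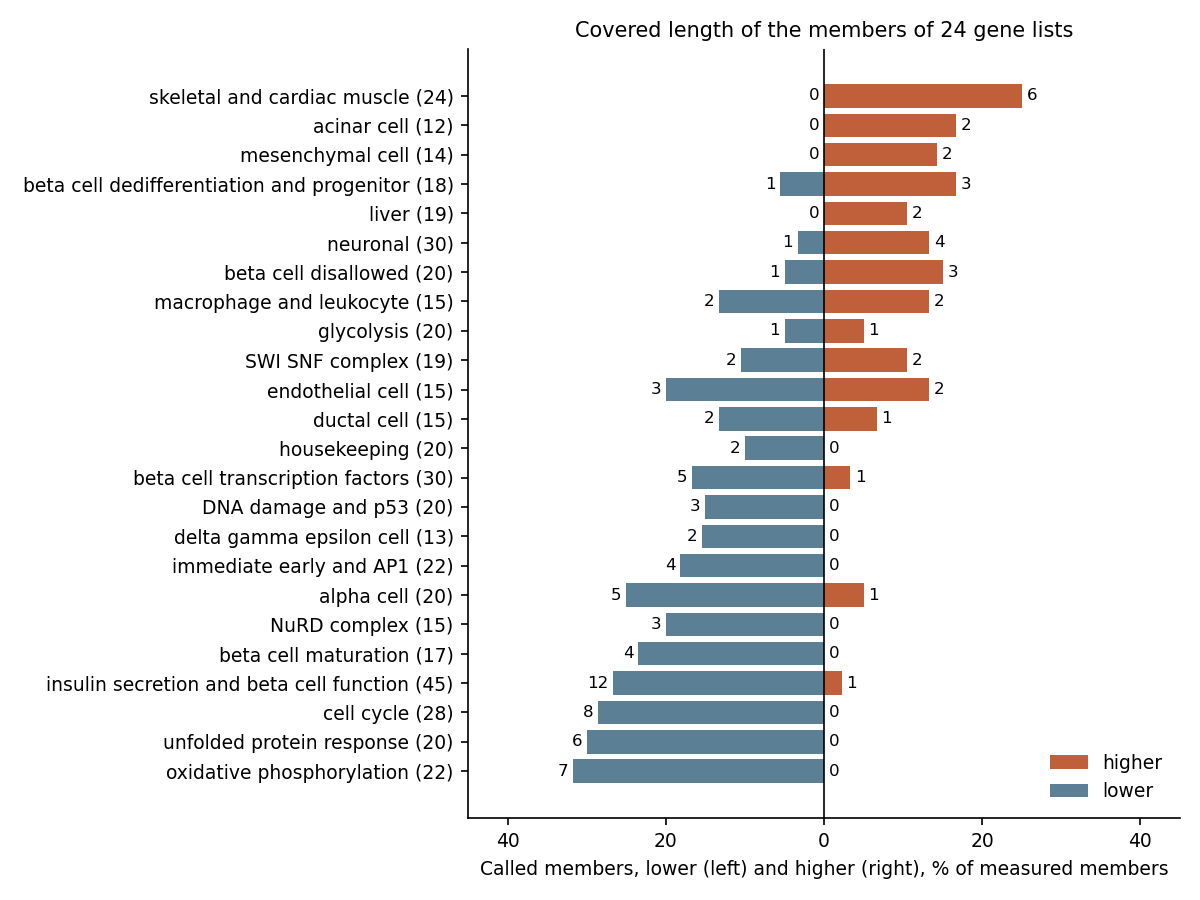
Share of measured members of 24 gene lists that were lower (left, blue) or higher (right, orange) in the knockout at a limma adjusted p under 0.05, with the number of members at each bar and of measured genes in brackets. Of all 17711 genes 2577 were lower and 1340 higher. Of 45 insulin secretion genes 12 were lower and 1 higher, which became 3 and 2 without scaling. With 1 library left out in turn, 4 to 9 were lower.

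Tested with fry, which asks whether a list itself differs between the groups, 6 lists were lower. These were the cell cycle, unfolded protein response, immediate early and DNA damage lists (fry adjusted p = 0.019 each) and the insulin secretion and maturation lists (fry adjusted p = 0.031 each). Without scaling none of these 6 passed, and the endothelial (fry adjusted p = 0.026), mesenchymal (fry adjusted p = 0.012) and muscle lists (fry adjusted p = 0.048) were higher. Fry does not set a list against the other genes. The median of all genes was -0.09 with scaling and 0.06 without, so a list can pass fry through this shift. With scaling, camera can place a list above other genes while its own values are negative. It did so for the α-cell, disallowed, ductal, endothelial, NuRD and SWI/SNF lists, whose medians and means were negative. The median and the mean differed in sign for the δ-, γ- and ε-cell list (-0.11 and 0.03), the macrophage list (-0.13 and 0.04) and the mesenchymal list (-0.0088 and 0.047).

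Counting gained and lost regions around list members, which uses no peak widths, put no list past the threshold against random lists with as many regions. The neuronal genes held 123 gained regions where random lists held 90.1 ± 11.4 (SD over 10000 lists, permutation p = 0.010, adjusted p = 0.31), and 42 lost regions where random lists held 29.9 ± 5.9 (permutation p = 0.058, adjusted p = 0.54). Assigned to the nearest gene span alone, the lost regions of the neuronal list had the smaller p (permutation p = 0.025 against 0.065 for gained regions, adjusted p = 0.29 and 0.46). Without control library 3 the lost regions had a permutation p = 0.0074 (adjusted p = 0.19). The insulin secretion genes held 47 gained regions where random lists held 66.5 ± 9.3 (permutation p = 0.026, adjusted p = 0.31), and the β-cell transcription factor genes 25 where random lists held 41.7 ± 7.4 (permutation p = 0.019, adjusted p = 0.31). The immediate early genes held 3 gained regions where random lists held 9.75 ± 3.1 (permutation p = 0.019, adjusted p = 0.31). With the 50000 strongest peaks per library, the insulin secretion genes held 27 gained regions against 25.5 (permutation p = 0.82), the transcription factor genes 12 against 14.5 (permutation p = 0.66) and the immediate early genes 2 against 4.33 (permutation p = 0.38). For the insulin secretion genes, a −log10 q of at least 5 gave 54 against 68.6 (permutation p = 0.13) and regions from summits 59 against 72.1 (permutation p = 0.18). For the transcription factor genes, a −log10 q of at least 5 gave 32 against 41.9 (permutation p = 0.19), a peak over at least 50% of the region 38 against 47.9 (permutation p = 0.24) and leaving out control library 2 gave 40 against 48.3 (permutation p = 0.33). Assigned to the nearest gene span, the immediate early genes had 14 against 18.1 (permutation p = 0.39). Without control library 2, the neuronal list passed for gained regions (permutation test, adjusted p = 0.029).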

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

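The gene territories other than the span plus 10 kb, the 5 kb gene ends and the assignment to the nearest gene span were chosen after the annotation had been seen. Territories around transcription starts and all motif tests were intended but not run, because neither strand nor sequence was used here. The excess of knockout peaks, the excess of gained over lost regions and the higher share of gained regions between genes kept their direction, except that lists cut to 50000 peaks are equally long by construction and leave no excess of peaks. Of 99 named genes past the threshold, 23 kept direction and call under every alternative that gave them a value. Only 6 of these had a value under all of them, Ins1, Camk2a, Dpysl4, Erg, Grin2b and Ryr1. Over the alternatives for these genes 1107 values kept direction and call, 385 lost the call and 28 changed sign. The depth in reads is unknown, so whether lost calls at weak peaks reflect depth was not tested.

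With a −log10 q of at least 5, gained regions were 101 and lost regions 24.1 times the expected number. With the 50000 strongest peaks these ratios were 133 and 38.8, with 5782 gained regions, 1543 genes with lower covered length and 0 gene lists, and the odds ratio at gene ends was 0.730 for gained and 1.02 for lost regions. Regions joined from summits gave ratios of 62.5 and 17.8 and odds ratios at gene ends of 0.458 for gained and 0.824 for lost regions, and of 1.02 between genes for lost regions. A peak over at least 50% of the region gave ratios of 80.3 and 19.8 and an odds ratio at gene ends of 0.778 for gained regions. Gene ends of 5 kb gave an odds ratio of 1.04 for gained regions. Without scaling, 2586 genes were higher and 510 lower, and quantile normalization gave 1314 lower genes. The number of gene lists past the threshold was 0 for each of these scalings, for the gene span plus 50 kb and without a filter on low values. The cause was not tested for any of these changes except scaling, where the median of all genes moves by construction.

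Leaving out each library in turn gave ratios to the expected number of 92.1 to 187 for gained and 36.8 to 88.7 for lost regions, with 4819 to 6188 lost regions. The odds ratio at gene ends for gained regions was 0.588 to 0.728. Higher genes numbered 676 to 1159 and lower genes 840 to 2229, lists 0 to 3, and lists with changed region counts 0 to 1. The low counts of genes came without control library 3 and without knockout library 1, and 6188 lost regions came without control library 1. With a library left out, a region needs to be called in fewer libraries, and fewer samples enter each fit.

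Same-numbered control and knockout libraries deviated together with correlations across genes of 0.13, 0.09 and -0.03, and control 3 correlated best with knockout 2 (0.08), so the numbers are not known to pair the samples. With the replicate number as a block, 1164 genes were higher, 1937 lower and 2 lists past the threshold, the muscle list being added. The exact paired sign-flip test of peaks per library cannot go below p = 0.25.

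Named genes that changed sign follow as log2 fold changes. With the 50000 strongest peaks these were Chd4 0.0639, Neurod1 0.00754, Slc2a2 0.29, Slc30a8 0.31, Glp1r 0.31, Irx2 0.27, Hhex 0.67, Cd74 -0.77, Pdgfrb -1.22, Myh6 -0.19, Hpd -0.14, Hdac2 0.0408, Mta1 0.0624, Smarcc1 -0.35, Arid1b 0.16, Plk1 0.00748, Atp5a1 0.20, Egr1 0.0838, Fosl2 0.00392 and Psmb2 0.16. With the gene span plus 50 kb these were Pdx1 -0.17, Nkx6-1 0.0820, Glp1r 0.0209, Sst 0.11, Npy1r 0.10, C1qc 0.10, Myh6 -0.10, Hpd -0.0478, Trp53 0.00186, Mcm3 0.0653, Egr1 0.10, Fosl2 0.0582 and Sdha 0.0902. With the gene span alone these were Pdx1 -0.15, G6pc2 0.0619 and Hpd -0.20. Without scaling these were Chd4 0.00542, Slc2a2 0.0135 and Slc30a8 0.0613. The cause was not tested.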

Other observations

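The tests of list length, of scaling, of gene length, of mean covered length and of lost regions near each other, and the counts over other splits of genes and regions, were chosen after the results they concern had been seen. Gene families sharing the start of their symbol were examined as well. Keratin genes (36 measured, prefix Krt) had 11 higher and 0 lower members and a median log2 fold change of 0.15 (camera adjusted p = 3.0e-05, or 0.88 with an estimated correlation). Their territories held 22 gained and 0 lost regions, where a region shared by neighboring genes counts once for each. Serpina genes, which encode serine protease inhibitors such as α1-antitrypsin, had 7 higher of 15 and a median of 0.38 (camera adjusted p = 3.0e-05; adjusted p = 0.88 with an estimated correlation). Both families also passed without scaling (camera adjusted p = 0.0098 and 0.028). Olfactory receptor genes had 21 higher and 7 lower of 116, with a median of -0.01 but a mean of 0.17. Of 128 families, 6 passed camera, all higher, and 0 passed with an estimated correlation. The prediction that a single passing family would exclude chance was too weak, because members of a family lie side by side and share peaks, so chance stays open.

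Set against 10000 random lists matched on gene length, the muscle list had a median log2 fold change of 0.11 at percentile 99.99 (permutation p = 4.0e-04, adjusted p = 0.0096), and matched on mean covered length it lay at percentile 99.82 (adjusted p = 0.046). The liver list lay at percentiles 99.81 (adjusted p = 0.048) and 97.83 (adjusted p = 0.24). The insulin secretion list lay at percentiles 2.02 and 2.59 (adjusted p = 0.195 and 0.241). For these positions genes were drawn and libraries were not exchanged, so they do not measure the spread between libraries. The random lists were matched on gene length or covered length alone. Myh6 and Myh7 in the muscle list have overlapping territories and are not independent. Gained regions were 2.98 times as many as lost regions on chromosome 14 and 6.30 times on the X chromosome. The 1-Mb window with most gained regions (chromosome 5, 112000001 to 113000000) held 31, with the crystallin genes Cryba4 and Crybb1 and Myo18b among its genes.

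The knockout libraries had 3.94 times as many gained as lost regions. In every knockout list, peaks of gained regions had a median percentile of at least 32.9. This lay above the bound of 25 set for peaks called only at the tail of longer lists. Most of these peaks therefore lay above the lowest 25% of the lists. Calling in all 3 libraries may itself favor peaks above the tail, so the bound does not decide how many stem from longer lists. Peaks of lost regions, selected in the same way, had 21.7 to 27.99 in the control lists, on both sides of the bound. Greater depth may contribute. Regions called in all 6 libraries differed by 8.77 bp in mean covered length, within the spread of the libraries. Control library 2 exceeded knockout libraries 1 and 3 in this length. Peaks of these regions had a median −log10 q of 82.5 to 102 in the knockout lists and 60.9 to 66.8 in the control lists, without overlap. Greater depth or higher signal over background could give such a difference, and read counts to test this are not available. With lists of 50000 peaks the ratio was 1.27, between the bounds set for and against list length, so Chd4 loss and longer lists cannot be told apart as the source of the excess.

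Insulin secretion genes had 12 lower members. Without scaling the list median was 0.0135 in place of -0.15 and 3 members were lower, but leaving out the scaling also moved the median of all genes by 0.15, so the change of the list decides nothing. Relative to the median of all genes the list lay at -0.06 with and -0.05 without scaling, and whether scaling or Chd4 loss sets its lower values cannot be told apart. At Ins1 the log2 fold change without scaling was -0.463 with a limma adjusted p of 0.0058, which argues against scaling as the cause there. A loss of accessible sequence at Ins1 after Chd4 loss is therefore a hypothesis that these tables leave standing, found and tested on the same data.

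The neuronal list passed camera, and its genes are long, with a median span of 1072 kb. Among random lists matched on gene length its median lay at percentile 82.01, so gene length is a candidate explanation for the call. Matched on mean covered length it lay at percentile 99.95 (adjusted p = 0.029). Genes were drawn for these positions too, so they do not measure the spread between libraries. The genotype split had 1 list past the threshold. Of the 10 splits of the 6 libraries, 7 had at least as many, the genotype split itself included, and the highest other had 3. With 10 splits chance cannot reach a share under 0.05.

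Around the 7 lists of other islet, pancreas, vessel, blood and connective tissue cells, 67 gained regions lay where matched random lists held 55.0 ± 7.4 (permutation p = 0.12). Assigned to the nearest gene span, 138 lay where random lists held 112 (permutation p = 0.023). With the 50000 strongest peaks 27 gained regions stood against 17.1 (permutation p = 0.029) and 8 lost regions against 17.97 (permutation p = 0.012). The other alternatives did not pass (permutation p for gained regions from 0.066 to 0.73), with 64 against 61.0 for regions from summits and 73 against 62.6 for a peak over at least 50% of the region. No such list passed alone, so cells of another type and chromatin changes in β-cells cannot be told apart from these counts. The cells were sorted for Tomato, but how many cells of another type remained was not measured here. Of the 122 genes, 8 stand in another list as well, and expression was not measured either. Gained regions had another gained region within 10 kb in 15.6% of cases, below the 17.1% to 19.5% of random placements, opposite to what closeness predicts. Lost regions did so in 7.68%, above the 3.62% to 6.56% of random placements. The placements kept the number of regions per chromosome but not their location within or between genes. They argue against chance placement of lost regions in that sense alone.

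Other splits of the libraries into 3 and 3 number 10 with the genotype split, too few for a share under 0.05. The genotype split called 3917 genes and the highest other 0 (limma, 7062 and at most 576 at an unadjusted p under 0.05), so no other split had as many. Gained regions numbered 16193 and the larger side of any other split at most 478. Lost regions numbered 4113 and the smaller side of any other split at most 157, so here too no other split had as many.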
